A study of Mus musculus with 56 samples.

How the data were processed

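Regulatory T cell RNA was measured by bulk sequencing in 56 libraries of 20 groups, 51 from mice and 5 from cultures. Per the labels, cells were sorted a second time to give 1000 cells per library, cDNA was made from poly(A) RNA and amplified, libraries went through 18 PCR cycles, and paired reads of 38 bases were sequenced. The cultures held VAT Tregs kept for 3 days with 10 ng/ml IL-33 and 2000 U/ml IL-2, with 0 or 50 ng/ml IFNα. The deposited values are raw counts per gene symbol, made per the submitters' processing notes with STAR 2.7.3a and featureCounts on mm10. The values were whole numbers whose totals differed between libraries. The annotation release, the strand setting and the handling of reads that match several genes are not given in the sources used here, so genes with near-identical copies (Ifit3 and Ifit3b, the guanylate-binding genes, H2-K1 and H2-D1, Hspa1a and Hspa1b, the Oas genes) and genes with overlapping neighbours have uncertain values. Of 55011 gene symbols 52936 (96.2%) matched GENCODE M21, which gave gene positions in mm10.

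Groups and replicate numbers came from the titles. No library lacked a group, and 0 columns lacked a sample. Libraries from the spleen by title carry the VAT tissue label too, and the titles were used. Pparg was at 0 to 7.76 CPM in the 26 spleen libraries and 17.8 to 122 CPM in the 25 VAT libraries. Total counts per library and the CPM worth of 3 counts are given with the results. Mitochondrial genes took 0.950 to 1.56% of counts in spleen and 0.844 to 1.21% in VAT.

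Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM normalization, filterByExpr by group, robust quasi-likelihood fits of group means). VAT libraries, spleen libraries, both tissues together and cultures were fitted separately, with 14164, 14686, 15601 and 12604 genes. The 14 comparisons were HFD against NCD in each tissue at weeks 2, 4, 8 and 16 and as the equally weighted mean of these weeks, the difference of the mean effects between tissues, VAT against spleen over week 0 and the NCD weeks, NCD week 16 against week 0 in VAT, and IFNα against control in culture. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. The SE of a log2 fold change is its size divided by the square root of the F statistic.

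Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01 between genes and again with an estimated one, adjusted over the lists of a comparison, where at least 3 members were measured. The 26 fixed lists were 16 of Treg biology (VAT-Treg programme, lymphoid and resting T cell, Treg core, type I interferon, guanylate-binding and antigen presentation, cell cycle, p53, fatty acid uptake, fatty acid oxidation, sterol and fatty acid synthesis, oxidative phosphorylation, glycolysis, T cell receptor, NF-kB, IL-2 and helper T cell effector), 1 of immediate early and heat shock genes and 9 of other cell types (B cell, macrophage, dendritic, NK and CD8 cell, granulocyte, adipocyte, stromal, endothelial and erythroid). Of their symbols 6 were missing from the table. Another 4 lists came from libraries outside the tested comparison, with an absolute log2 fold change of at least 1: 381 genes higher and 427 lower with IFNα in culture, and 1607 higher and 1155 lower in VAT than spleen at week 0. List calls were also counted with p adjusted over the list alone.

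Named genes were, per comparison, the 10 rising and 10 falling genes with the smallest p among those called, changed at least 2-fold, with a mean log2 CPM of at least 3 and no overlap between the arms (over several weeks, the same sign in every week). Predicted genes, pseudogenes, ribosomal protein genes and receptor variable segments were left out. To these were added the 3 members with the smallest p of each list that passed, and always Foxp3, Pparg, Il1rl1, Klrg1, Gata3, Il10, Isg15, Ifit3, Irf7, Mki67, Ccr2, Areg and Cd36. Some genes that the rule named are not reported here. The groups, comparisons, tests, lists, this rule and the first set of alternatives were fixed before the data were examined.

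The alternatives were RLE normalization, no filter, DESeq2 1.42.0, limma voom with quality weights, a fit of only the groups compared, the replicate number as a block, and leaving out each library. Chosen after seeing the data were a correction of GC content per library, fits without week 4 or week 16, the mean of the stress genes as a covariate, and the mean of the genes higher with HFD in spleen at week 4 as a covariate. Where leaving out a library left 1 in an arm, that library was assumed to vary like the other groups. Each comparison was tested on simulated counts of matching size with 100 genes changed 2-fold and 100 changed 4-fold. Simulated genes were drawn independently of each other, so false calls from variation shared between genes were not tested. For VAT week 16, edgeR found 29 and 75 of them among 13669 simulated genes with 2 false calls, and for the VAT mean 75 and 92 among 13690 with 16. The GC correction, tested on 13912 simulated genes with a GC trend, brought false calls from 2832 to 2.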

Results

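Gene expression was measured in mouse regulatory T cells (Tregs, the CD4 T cells that restrain immune responses and depend on the transcription factor Foxp3), in a series about Treg transcription in obesity. The mice carried vTreg53, a transgenic T cell receptor, and were fed 1 of the diets abbreviated NCD and HFD from 12 weeks of age for 2, 4, 8 or 16 weeks, or were taken at week 0. Tregs bearing the transgenic receptor were sorted from spleen and from visceral adipose tissue (VAT), with 1000 cells per library. The 26 spleen and 25 VAT libraries fell into 9 groups per tissue, each of 3 libraries except NCD week 4 in spleen, HFD week 4 in VAT and NCD week 16 in VAT, which had 2. A further 5 libraries held VAT Tregs of another mouse line cultured for 3 days, 3 without and 2 with interferon-α (IFNα). Total counts ran from 3248686 to 5826965 per spleen library, 3319873 to 6091439 per VAT library and 5408696 to 8764390 per culture. A count of 3, taken as the floor of detection, was worth 0.492 to 0.923 CPM (counts scaled to library size) in the spleen and VAT libraries. Floors cover counting error only. Levels are mean CPM ± SD over libraries and changes are log2 fold changes ± SE from edgeR. Whether replicates came from separate mice is not stated, so p-values measure only the spread between these libraries.

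Tregs of VAT and spleen were compared without HFD, over week 0 and the 4 NCD weeks, to set the diet effects beside the difference between tissues. Areg, the gene of the tissue-repair factor amphiregulin, averaged 1128 ± 398 CPM in VAT (SD, n = 14) and 1.82 ± 2.09 in spleen (SD, n = 14), a change of 9.94 ± 0.31 (edgeR adjusted p = 4.04e-24). Pparg, which encodes a lipid-sensing nuclear receptor, was higher in VAT too, at 105 against 1.35 CPM (adjusted p = 9.07e-18). The fitted changes of Areg and Pparg (7.46) average 5 groups per tissue, of which some have few or no counts in spleen, and depend on how counts near 0 are treated. Il1rl1, the receptor gene for IL-33, was higher by 4.96 ± 0.20, Klrg1, a marker of matured Tregs, by 3.59 ± 0.21, and Foxp3 itself by 0.54 ± 0.039. Of 44 genes of the type I interferon response 39 were lower in VAT. All 18 of 18 genes of the VAT-Treg programme were higher (list median 3.68). Genes induced within minutes of stress or activation stood out too: Junb reached 10006 CPM in VAT against 318 in spleen, and 19 of 20 immediate early and heat shock genes were higher (list median 4.34). By edgeR, 9221 of 15601 genes differed, 4533 higher and 4688 lower in VAT. The directions of these 3 lists held in camera with an estimated correlation between genes (adjusted p = 0.00933 for interferon, 0.00142 for the VAT-Treg programme and 1.22e-06 for the immediate early genes), as did those of the lymphoid, fatty acid uptake, fatty acid oxidation, T cell receptor and IL-2 lists. Ifit3 shares sequence with Ifit3b and the guanylate-binding genes with each other, and how reads matching several genes were counted is not given in the sources used here, so values of such families are uncertain.

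After 2 weeks of diet the VAT Tregs differed in few genes. Ndrg1, a gene raised by T cell activation and low oxygen, rose from 113 ± 24.7 (SD, n = 3) with NCD to 234 ± 8.76 CPM (SD, n = 3) with HFD, a change of 1.05 ± 0.14 (edgeR adjusted p = 5.85e-04). Furin, which encodes a protease that activates TGF-β, rose by 1.38 ± 0.20 and the actin regulator Cotl1 by 1.16 ± 0.18 (adjusted p = 0.00112 and 0.00426). Pparg (0.34 ± 0.31) and Il10 (1.08 ± 0.53) did not pass the test. In all, 8 of 14164 genes passed in edgeR, each higher with HFD. The VAT-Treg programme (list median 0.37), the NF-kB response (0.24), oxidative phosphorylation (0.25) and the immediate early and heat shock genes (0.40) passed in camera with the preset correlation (adjusted p = 7.29e-08, 1.26e-06, 7.02e-06 and 1.61e-06). None of the 4 did so with an estimated one (adjusted p = 0.0798, 0.0798, 0.251 and 0.151 with an estimated correlation). The cell cycle, p53, fatty acid oxidation, T cell receptor, IFNα-lower, VAT-higher and VAT-lower lists likewise passed with the preset one alone. The median of the VAT-Treg programme was 0.60 without NCD replicate 1 and 0.21 without NCD replicate 2, that of NF-kB 0.14 without NCD replicate 1 and 0.41 without NCD replicate 3 and that of oxidative phosphorylation 0.15 without NCD replicate 2. The count was 54 without NCD replicate 1, 4 without NCD replicate 2, 30 without NCD replicate 3 and 2 without HFD replicate 1. With the mean of the genes higher with HFD at spleen week 4 as a covariate the count was 3, and Furin (1.20) and Cotl1 (1.03) lost their calls. Cotl1 also lost its call without HFD replicate 1 (1.05), and Il10 gained one without NCD replicate 1 (2.34).

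At week 4 in VAT, Ctla4, the gene of an inhibitory receptor central to Treg function, rose from 2135 ± 124 CPM (SD, n = 3) to 3301 ± 73.0 CPM (SD, n = 2), a change of 0.63 ± 0.10 (edgeR adjusted p = 0.0186). Echdc2, a gene of mitochondrial lipid metabolism, rose by 1.75 ± 0.30 (adjusted p = 0.0245). The remaining call, Parp8, was lower with HFD (adjusted p = 0.0497). Parp8 is named here because so few genes passed, after its values were seen, and its fitted change of -7.67 ± 1.41 depends on how counts near 0 are treated. Klrg1 (0.58 ± 0.17) and Ccr2 (0.53 ± 0.18) did not pass. These were 3 of 14164 genes in edgeR, 1385 being under an unadjusted p of 0.05 (708.2 expected with no effect). The lymphoid and resting T cell list had a median of -1.26 (camera adjusted p = 3.51e-07, or adjusted p = 0.246 with an estimated correlation). Among other lists, Treg core, T cell receptor, fatty acid oxidation, cell cycle, sterol and helper T cell genes also passed with the preset correlation. With 1 library left out, the median was 0.246 to 0.312 for Treg core and -0.912 to -0.592 for cell cycle genes. Ctla4 lost its call without NCD replicate 1 (0.58), HFD replicate 2 (0.60) and HFD replicate 3 (0.64), Echdc2 without NCD replicate 1 (1.65), NCD replicate 2 (1.71) and HFD replicate 2 (1.37) and Parp8 without NCD replicate 1 (-7.63), NCD replicate 2 (-7.36), HFD replicate 2 (-7.69) and HFD replicate 3 (-7.68). The edgeR count was 0 without NCD replicate 1, 0 without HFD replicate 2 and 6 without HFD replicate 3.

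At week 8 in VAT, Tnfrsf9 and Pdcd1 were among the genes that rose with HFD and Sqle and Srebf2 among those that fell. Tnfrsf9, which encodes the costimulatory receptor 4-1BB, rose from 245 ± 55.1 (SD, n = 3) to 584 ± 36.6 CPM (SD, n = 3), a change of 1.25 ± 0.15 (edgeR adjusted p = 1.43e-04). The inhibitory receptor gene Pdcd1 rose by 1.04 ± 0.15, the cathepsin gene Ctss by 1.65 ± 0.21, and Lrrc32, whose product presents TGF-β on activated Tregs, by 2.29 ± 0.36 (adjusted p = 5.88e-04, 2.95e-04 and 0.00297). Sqle, which encodes an enzyme of cholesterol synthesis, fell by 1.16 ± 0.26, and Srebf2, the master regulator of that pathway, fell by 0.59 ± 0.12 (adjusted p = 0.0221 and 0.00879). Of 14164 genes tested, edgeR called 189, 118 higher and 71 lower with HFD. Treg core genes rose as a list (median 0.36, 4 of 16 called, 12 when adjusted over the list alone, camera adjusted p = 4.07e-11 and 1.83e-04 with an estimated correlation), and so did genes lower in VAT than spleen at week 0 (median 0.32, adjusted p = 0.0492 with an estimated correlation). The sterol list had a median of -0.44 and passed only with the preset correlation (median -0.28 without NCD replicate 2, adjusted p = 1.17e-06, against adjusted p = 0.203 with an estimated correlation), as did the lymphoid, interferon, guanylate-binding, cell cycle, p53, T cell receptor, NF-kB, IFNα-higher, IFNα-lower and VAT-higher lists. Single libraries moved the count to 37 without NCD replicate 2, 47 without HFD replicate 1, 102 without HFD replicate 2 and 66 without HFD replicate 3. With the mean of the genes higher at spleen week 4 as a covariate it was 38, and Sqle (-0.91) and Srebf2 (-0.54) lost their calls. Sqle also lost its call without NCD replicate 1 (-1.04), NCD replicate 2 (-0.99), HFD replicate 1 (-1.03) and HFD replicate 3 (-1.17) and Srebf2 without NCD replicate 2 (-0.49) and HFD replicate 1 (-0.56).

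The week 16 comparison in VAT gave the most called genes of the weekly comparisons, and many of them also differed between VAT and spleen. Ctss (chromosome 3, 95526786 to 95556403 in mm10), low in VAT Tregs without HFD, rose from 27.5 ± 8.31 (SD, n = 2) to 324 ± 77.6 CPM (SD, n = 3), a change of 3.55 ± 0.27 (edgeR adjusted p = 1.70e-08). The lymphotoxin gene Ltb rose by 1.57 ± 0.15 (adjusted p = 9.67e-08). Genes that mark VAT Tregs fell: Pparg (chromosome 6, 115360951 to 115490399) dropped from 110.1 ± 8.90 (SD, n = 2) to 30.1 ± 18.3 CPM (SD, n = 3), a change of -1.86 ± 0.35 (adjusted p = 0.00136). Il1rl1 changed by -1.37 ± 0.25, Klrg1 by -1.12 ± 0.16, the chemokine receptor gene Ccr2 by -1.43 ± 0.18 and Il10, the gene of an inhibitory cytokine, by -2.89 ± 0.59 (adjusted p = 0.00131, 7.98e-05, 1.90e-05 and 0.00419). Foxp3 (-0.12 ± 0.10, adjusted p = 0.548) and Gata3 (-0.66 ± 0.26, adjusted p = 0.145) did not pass. In edgeR, 1309 of 14164 genes passed, 611 higher and 698 lower with HFD. Of genes higher in VAT than spleen at week 0, 302 of 1607 fell and 44 rose, and of genes lower in VAT 239 of 1070 rose and 1 fell. The count was 671 without NCD replicate 2 and 643 without NCD replicate 3. With the mean of the immediate early and heat shock genes as a covariate, Pparg (-1.29), Il1rl1 (-0.38), Klrg1 (-0.94) and Il10 (-3.23) lost their calls. Il10 lost its call without NCD replicate 2 (-2.49) and Gata3 gained one without HFD replicate 2 (-0.98).

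Interferon genes were among those that rose in VAT at week 16. Rtp4, an interferon-induced chaperone gene, increased from 2.17 ± 2.48 (SD, n = 2) to 44.1 ± 9.78 CPM (SD, n = 3), a change of 4.28 ± 0.62 (edgeR adjusted p = 5.28e-05). It had few counts with NCD, so the size of this change depends on how counts near 0 are treated. The RNA sensor gene Ifih1 rose by 2.02 ± 0.36 (adjusted p = 4.11e-04). Ifit3 (2.72 ± 1.04, adjusted p = 0.116), Irf7 (0.95 ± 0.32, 0.0644) and Isg15 (0.99 ± 0.59, 0.358) did not pass. Irf7 passed without HFD replicate 2 (1.08) and Ifit3 without NCD replicate 2 (8.55), a fitted value from counts near 0, and Rtp4 was 6.63 without NCD replicate 2. Across the type I interferon list 18 of 44 genes rose (23 higher and 1 lower when adjusted over the list alone), with a median of 0.97. Of the guanylate-binding and antigen presentation list 18 of 25 rose (median 1.01), and of genes raised by IFNα in culture 88 of 324 rose and 13 fell. All 3 lists passed in camera with an estimated correlation (adjusted p = 0.0255, 0.0261 and 0.0110).

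Lipid and stress genes fell in the same comparison. Sqle went from 103 ± 19.6 (SD, n = 2) to 19.0 ± 6.43 CPM (SD, n = 3), a change of -2.43 ± 0.29 (edgeR adjusted p = 5.62e-06). Of the sterol and fatty acid synthesis list 15 of 22 genes fell (16 when adjusted over the list alone, median -1.01). The fatty acid uptake and storage list had a median of -0.73. The VAT-Treg programme (11 of 18 lower, median -1.19) and the immediate early and heat shock genes (11 of 20 lower, median -1.07) fell, while the Treg core list (median 0.30, 5 higher and 3 lower) moved up. These 5 lists passed with an estimated correlation (adjusted p = 0.0140, 0.0261, 0.00784, 0.0110 and 0.0130). Lymphoid (1.75), NF-kB (0.23), IL-2 (-0.38) and fatty acid oxidation (-0.083) genes passed only with the preset one (adjusted p = 3.21e-06, 0.0263, 0.00677 and 0.0352, against adjusted p = 0.149, 0.314, 0.172 and 0.166 with an estimated correlation). Cell cycle (adjusted p = 0.653), p53 (0.942), oxidative phosphorylation (0.0560), glycolysis (0.101), T cell receptor (0.187), helper T cell (0.586) and IFNα-lower (0.181) lists did not pass in camera. The T cell receptor and IFNα-lower lists had medians of 0.11 and 0.029 although camera ranked them downward. With the mean of the stress genes as a covariate, fatty acid uptake lost its call (-0.53, preset adjusted p = 0.0870), as did the stress genes themselves (-0.013) by construction, and medians were 0.19 for Treg core, 0.50 for NF-kB, -0.22 for IL-2 and -0.27 for fatty acid oxidation. With the replicate number as a block they were 0.16 for Treg core and -0.14 for fatty acid oxidation, and with the mean of the genes higher at spleen week 4 as a covariate IL-2 was at -0.59 and fatty acid oxidation lost its call (-0.063). The lymphoid median was 0.92 without HFD replicate 3, that of IL-2 -0.18 without NCD replicate 2, that of Treg core 0.16 without HFD replicate 1 and that of fatty acid oxidation -0.16 without NCD replicate 2, -0.15 without HFD replicate 1 and -0.020 without HFD replicate 3. Fatty acid oxidation lost its call with the preset correlation without NCD replicate 3 (-0.065), HFD replicate 2 (-0.090) and HFD replicate 3 (-0.020), and NF-kB without NCD replicate 3 (0.27) and HFD replicate 2 (0.17).

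Genes of other cell types were checked in the same libraries. B cell genes were higher with HFD at week 16 (median 1.73, and 2.63 without HFD replicate 2, camera adjusted p = 0.0209, or adjusted p = 0.262 with an estimated correlation), with Cd79b at 15.2 against 2.10 CPM and Ighm, an antibody heavy chain gene, at 1909 against 335 CPM. The B cell call was lost without a filter (0.79, adjusted p = 0.131) and with the stress-gene covariate (2.58, adjusted p = 0.0914). Macrophage (adjusted p = 0.431), dendritic cell (0.942), NK and CD8 cell (0.568), adipocyte (0.106) and endothelial (0.942) lists did not pass. Granulocyte, stromal and erythroid lists had 2, 2 and 1 measured genes, under the 3 needed for a test. NK and CD8 cell genes were lower with HFD at week 8 (median -3.95, and -0.82 without NCD replicate 1, camera adjusted p = 3.49e-04, or adjusted p = 0.108 with an estimated correlation), where Ncr1 had no count in the HFD libraries and 6.43 CPM with NCD. That median was -1.42 without a filter and -0.44 in a fit of only the groups compared, where the B cell median was 2.86.

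**Figure D1:**
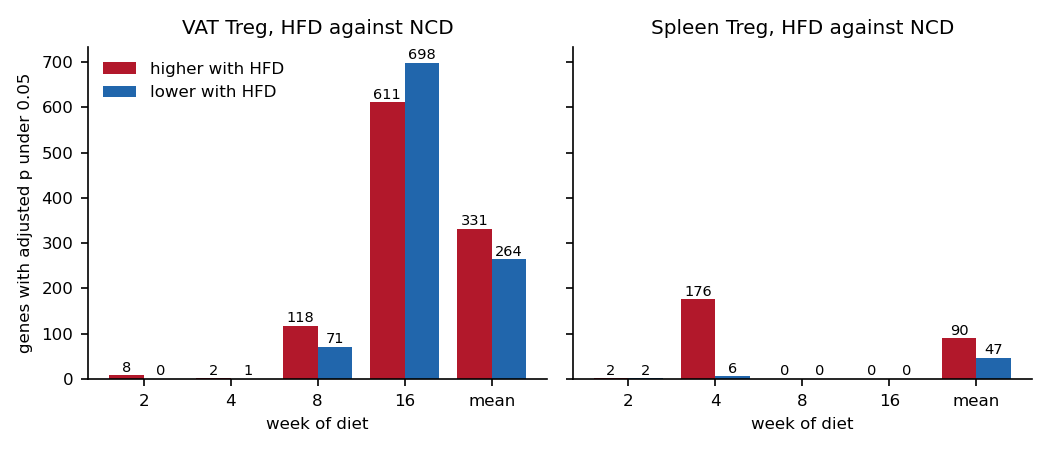
Number of genes called by edgeR for HFD against NCD in VAT and spleen at weeks 2, 4, 8 and 16 and over their mean. Red bars give genes that rose and the blue bars beside them genes that fell. VAT at week 16 has 1309 called genes, against 8 at week 2, 3 at week 4 and 189 at week 8.

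**Figure D2:**
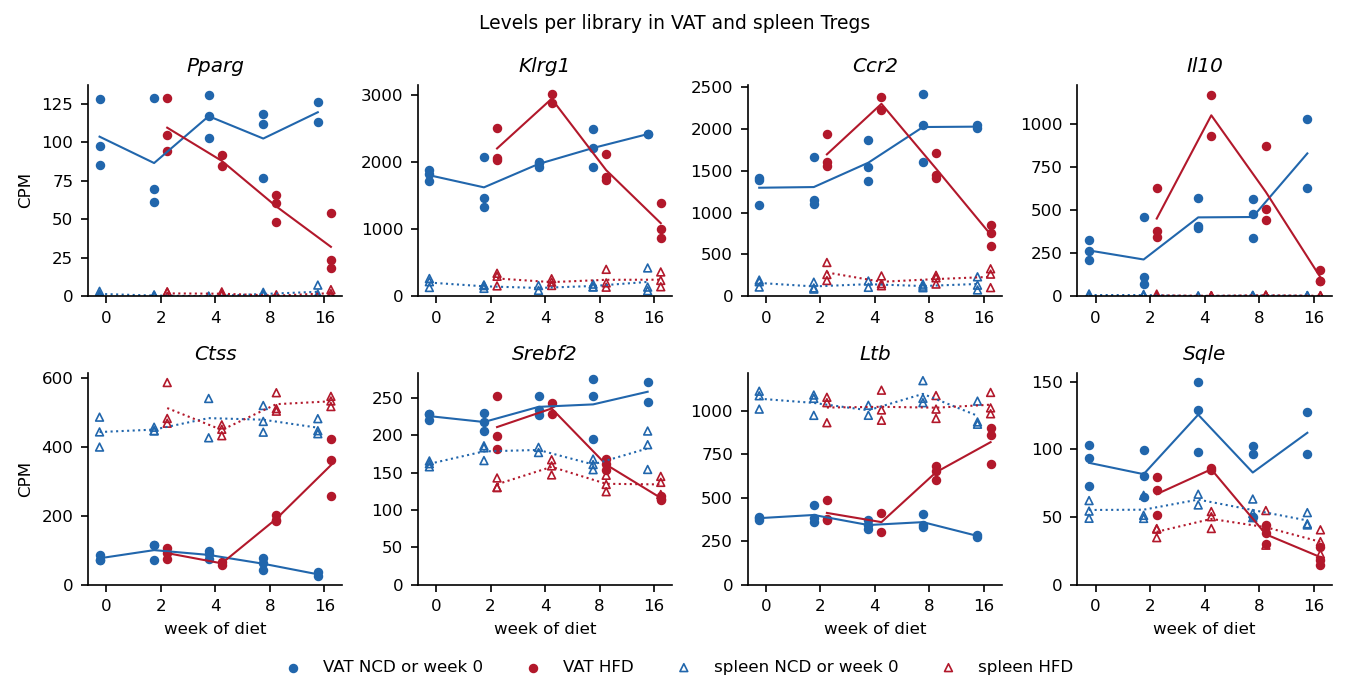
CPM of 8 genes per library against weeks of diet, with filled circles for VAT, open triangles for spleen, blue for NCD and week 0, red for HFD, and lines through group means. With both tissues normalized together, which gives values other than VAT alone, Pparg averages 119.3 CPM with NCD and 32.05 with HFD in VAT at week 16, and Ctss 29.8 and 346.1.

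Averaged over the 4 weeks, HFD lowered sterol genes in VAT and raised genes of NF-kB signalling and Treg identity. Sqle fell by 1.11 ± 0.14, from 92.2 ± 26.5 (SD, n = 11) to 45.8 ± 24.6 CPM (SD, n = 11) (edgeR adjusted p = 2.77e-05), and was lower with HFD in all 4 weeks. Egr1, an early gene of receptor signalling, changed by -1.14 ± 0.17 (adjusted p = 8.22e-04). Trf, the transferrin gene, rose by 1.51 ± 0.15, Ltb by 0.63 ± 0.066, Izumo1r (folate receptor 4, a Treg surface protein) by 0.81 ± 0.090 and Tnfrsf9 by 0.67 ± 0.080 (adjusted p = 1.69e-06, 1.69e-06, 3.87e-06 and 1.20e-05). Pparg changed by -0.69 ± 0.17 (adjusted p = 0.0212). Of 14164 genes edgeR called 595, 331 higher and 264 lower. The sterol list (13 of 22 lower, 17 when adjusted over the list alone, median -0.50), the Treg core list (9 of 16 higher, median 0.28), the NF-kB list (median 0.26) and the IFNα-higher list (median 0.15) passed in camera with an estimated correlation (adjusted p = 0.0294, 3.64e-05, 0.0294 and 0.0449). The glycolysis list passed only with the preset one (median 0.081, adjusted p = 0.00149, or adjusted p = 0.168 with an estimated correlation) and lost its call with the mean of the stress genes as a covariate (0.017, adjusted p = 0.0887), as did Pparg (-0.58). NK and CD8 cell genes and immediate early genes also passed with the preset one. With 1 library left out their medians were -2.97 to -0.770 and -0.287 to -0.201. The count was 372 without HFD week 4 replicate 2, and Pparg lost its call without NCD week 16 replicate 2 (-0.67), HFD week 4 replicate 2 (-0.70) and HFD week 4 replicate 3 (-0.68). Without week 16 the count was 162, and Pparg (-0.29) and Egr1 (-0.65) lost their calls, as did the IFNα-higher list (0.019, preset adjusted p = 0.109). The sterol list then had a median of -0.27, and the effect was -0.66 on Sqle, 0.32 on Ltb and 0.44 on Izumo1r.

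Spleen Tregs of the same weeks were tested to ask whether the diet acted outside fat. At week 2 Icos, a costimulatory receptor gene, rose from 215 ± 57.2 (SD, n = 3) to 449 ± 64.4 CPM (SD, n = 3), a change of 1.06 ± 0.17 (edgeR adjusted p = 0.0111). The mitochondrial carbonic anhydrase gene Car5b rose by 2.73 ± 0.49, and Unk, named after its values were seen, was lower with HFD (adjusted p = 0.0307 and 0.0307). The sterol list fell as a group (median -0.43, camera adjusted p = 0.00622 with an estimated correlation), and 4 of 14686 genes were called in edgeR. The edgeR count was 1 without NCD replicate 1, 0 without NCD replicate 2, 2 without NCD replicate 3, 0 without HFD replicate 1, 0 without HFD replicate 2 and 1 without HFD replicate 3. Icos lost its call without NCD replicate 2 (1.04), NCD replicate 3 (0.88), HFD replicate 1 (0.99) and HFD replicate 2 (1.02), Car5b without NCD replicate 1 (2.76), NCD replicate 2 (2.49), NCD replicate 3 (3.03), HFD replicate 1 (2.90), HFD replicate 2 (2.83) and HFD replicate 3 (2.44) and Unk without NCD replicate 1 (-0.96), NCD replicate 2 (-0.99), NCD replicate 3 (-1.04), HFD replicate 1 (-1.09), HFD replicate 2 (-1.03) and HFD replicate 3 (-0.86). At weeks 8 and 16 edgeR called 0 genes, with 716 and 975 genes under an unadjusted p of 0.05, against 734.3 expected with no effect. DESeq2 called 1 and 21 there, and limma voom 0 and 0. In the self-test of these weeks, edgeR found 69 and 62 of 100 genes changed 4-fold among 14169 and 14195 simulated genes. Of 100 genes changed 2-fold it found 42 and 44, so smaller effects could be missed. At week 8 the count was 1 without HFD replicate 1 and 7 without HFD replicate 3, and at week 16 1 without HFD replicate 3.

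At week 4 the spleen call list was long and nearly all upward. Lsm4, a gene of RNA splicing, went from 42.7 ± 6.34 (SD, n = 2) to 144 ± 4.93 CPM (SD, n = 3), a change of 1.76 ± 0.24 (edgeR adjusted p = 7.86e-04). The adiponectin receptor gene Adipor1 rose by 1.51 ± 0.22, the transcription factor gene Zbtb7a by 2.05 ± 0.31 and the mitochondrial DNA polymerase gene Polg by 1.30 ± 0.21 (adjusted p = 0.00169, 0.00171 and 0.00199). Of 14686 genes 176 rose and 6 fell, and 117 of the 176 were also higher in VAT than spleen at week 0. The mean difference of the 176 between VAT and spleen was 1.39 (log2) at week 0 and 1.39 at NCD week 4, but 0.176 at NCD week 2, 0.282 at week 8 and -0.179 at week 16. Genes lowered by IFNα in culture rose here as a list (median 0.39, camera adjusted p = 0.0254 with an estimated correlation), with a median of 0.60 without NCD replicate 1 and 0.23 without HFD replicate 3 and 0.24 without a filter. The mean of the 176 genes was 4.42 and 4.83 log2 CPM in the NCD libraries and 6.20 to 6.30 in the HFD libraries. Outside spleen week 4 that mean varied between replicates with an SD of 0.31. The edgeR count was 0 without NCD replicate 2 and 120 without HFD replicate 2. Without NCD replicate 2 (1.62) Lsm4 lost its call, as did Adipor1 (1.31), Zbtb7a (1.97) and Polg (1.28).

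Over the 4 weeks the spleen shared the fall of sterol genes. Hmgcs1, the gene of an early enzyme of the pathway, fell by 0.44 ± 0.078, from 123 ± 13.2 (SD, n = 11) to 92.8 ± 17.6 CPM (SD, n = 12) (edgeR adjusted p = 0.00956), and Srebf2 fell by 0.33 ± 0.056 (adjusted p = 0.00561). Cpt1a, which encodes the gatekeeper of mitochondrial fatty acid oxidation, rose by 0.76 ± 0.11 and Icos by 0.52 ± 0.087 (adjusted p = 0.00248 and 0.00623). Of 14686 genes edgeR called 137, 90 higher and 47 lower. The sterol list (median -0.24, 4 of 22 lower, 7 lower and 1 higher when adjusted over the list alone), the IFNα-lower list (median 0.22) and the VAT-higher list (median 0.30) passed in camera with an estimated correlation (adjusted p = 0.00524, 0.0430 and 0.0164). Cell cycle genes (median 1.06, adjusted p = 5.72e-20) did so only with the preset one (adjusted p = 0.0831 with an estimated correlation). The count moved with single libraries, to 70 without NCD week 2 replicate 2, 63 without NCD week 2 replicate 3, 16 without NCD week 4 replicate 2, 35 without NCD week 8 replicate 1, 283 without NCD week 16 replicate 1, 54 without NCD week 16 replicate 3, 91 without HFD week 2 replicate 1, 34 without HFD week 4 replicate 3, 37 without HFD week 8 replicate 1, 57 without HFD week 8 replicate 2, 240 without HFD week 8 replicate 3 and 35 without HFD week 16 replicate 1, and was 77 without week 4, where the IFNα-lower list had a median of 0.10, and 0.14 without a filter. With the mean of the genes higher at spleen week 4 as a covariate, which is built from some of these libraries, the count was 1, and Hmgcs1 (-0.42), Srebf2 (-0.31), Cpt1a (0.76) and Icos (0.51) lost their calls. The median was then 0.47 for cell cycle genes, 0.11 for the IFNα-lower list and 0.17 for the VAT-higher list.

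The effect of HFD in VAT was then compared with that in spleen directly, as the difference of the 2 mean effects. Izumo1r differed by 0.85 ± 0.10 and Ltb by 0.63 ± 0.078, toward VAT (edgeR adjusted p = 8.46e-07 and 1.39e-06). In the other direction were Lgals3 (galectin-3, -1.83 ± 0.27) and Car5b (-2.12 ± 0.27) (adjusted p = 1.19e-04 and 1.88e-06). Both were lower with HFD in VAT and higher with it in spleen. By edgeR 380 of 15601 genes differed, 169 upward and 211 downward. Genes higher in VAT at week 0 moved down in this contrast (median -0.37) and genes lower in VAT up (median 0.27), with camera adjusted p = 0.0129 and 0.00967 with an estimated correlation. The sterol list passed with the preset correlation, toward a larger fall in VAT. Its median was -0.280 to -0.208 with 1 library left out. Among 13360 genes tested in both tissues, 10 rose in both (2.19 expected of independent lists) and 5 fell in both (0.83 expected), while 4 fell in VAT and rose in spleen (1.61 expected) and 1 did the reverse (1.13 expected). The 5 included Sqle, Srebf2 and Hmgcs1, and the 10 included Icos, Nfil3 and Trf. These shared genes were singled out after their values were seen, and the tissues share no libraries. The number of genes was 216 without spleen NCD week 4 replicate 2 and 626 without week 4, and 220 with the mean of the genes higher at spleen week 4 as a covariate.

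**Figure D3:**
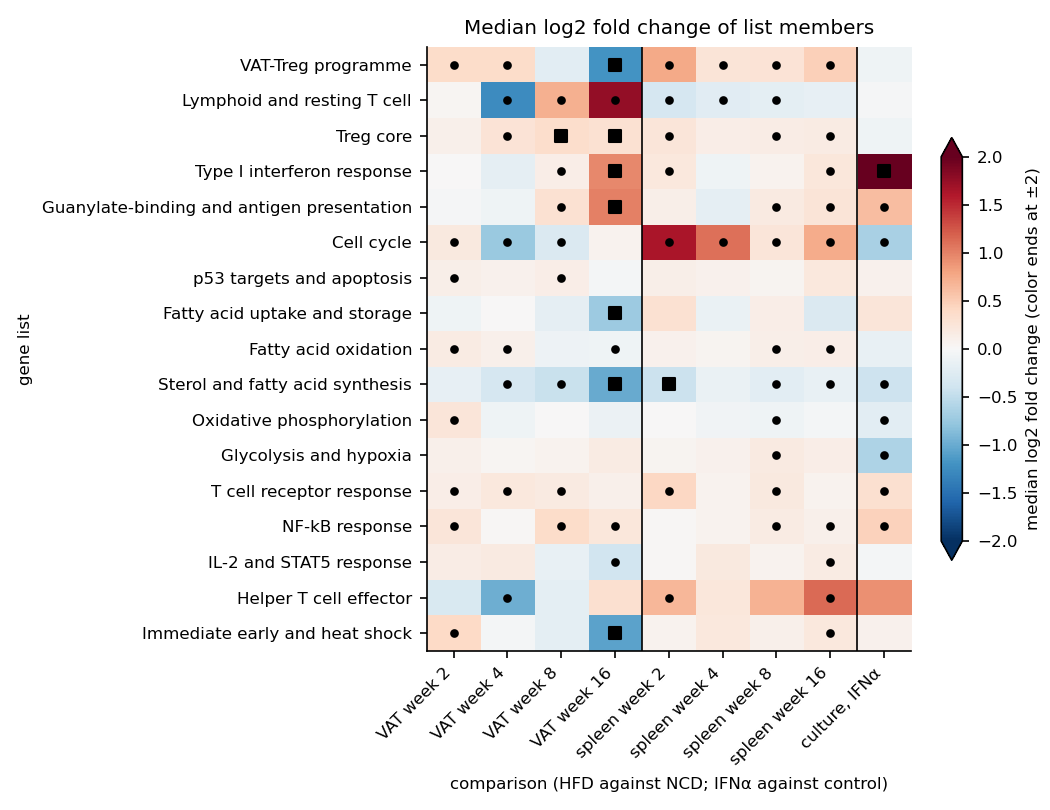
Median log2 fold change of 17 gene lists for HFD against NCD in each week and tissue and for IFNα in culture, on a colour scale ending at 2 in either direction, with dots where camera passed with the preset correlation and squares where it also passed with an estimated one. In VAT at week 16 the VAT-Treg programme stands at -1.19 and the type I interferon response at 0.97.

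Time on NCD alone was compared in VAT, week 16 against week 0, where age and time are the same variable. Lrrc32 changed from 95.3 ± 29.1 (SD, n = 3) to 13.1 ± 3.48 CPM (SD, n = 2), by -2.86 ± 0.44 (edgeR adjusted p = 0.00610). Pmaip1, a gene of cell death, rose by 1.20 ± 0.18, the glucocorticoid-induced gene Fkbp5 by 1.27 ± 0.20 and the stress gene Zfp36 by 1.30 ± 0.23 (adjusted p = 0.00277, 0.00298 and 0.00782). Ctss, which rose with HFD, fell here by 1.36 ± 0.26 (adjusted p = 0.0134). Of 14164 genes 64 were higher and 37 lower at week 16. The VAT-Treg programme had a median of 0.65 (camera adjusted p = 4.80e-09, or adjusted p = 0.0994 with an estimated correlation). The stress genes (median 0.50) also passed upward with the preset correlation, and the B cell (-1.98), lymphoid (-0.85), interferon (-0.24), guanylate-binding (-0.24), cell cycle (-0.73), NF-kB (-0.25) and helper T cell (-0.63) lists downward. With the preset correlation the lymphoid list lost its call without NCD week 16 replicate 3 (-0.69), interferon without NCD week 16 replicate 3 (-0.16), guanylate-binding without NCD week 16 replicate 3 (-0.23), NF-kB without week 0 replicate 2 (-0.23), week 0 replicate 3 (-0.23) and NCD week 16 replicate 3 (-0.24) and helper T cell without NCD week 16 replicate 3 (-0.86) and without a filter (-0.12). The median was 0.33 without NCD week 16 replicate 2 for stress genes, -0.47 without NCD week 16 replicate 2 and -1.18 without NCD week 16 replicate 3 for cell cycle genes and -1.73 without NCD week 16 replicate 2 for helper T cell genes. No list tested for time passed with an estimated correlation. Single libraries moved the count to 34 without week 0 replicate 1, 24 without week 0 replicate 2, 21 without week 0 replicate 3, 1 without NCD week 16 replicate 2 and 37 without NCD week 16 replicate 3. Lrrc32 lost its call without NCD week 16 replicate 2 (-3.17) and NCD week 16 replicate 3 (-2.63), Pmaip1 without NCD week 16 replicate 2 (1.17), Fkbp5 without NCD week 16 replicate 2 (1.38), Zfp36 without week 0 replicate 2 (1.25), week 0 replicate 3 (1.25) and NCD week 16 replicate 2 (1.17) and Ctss without week 0 replicate 2 (-1.27), NCD week 16 replicate 2 (-1.71) and NCD week 16 replicate 3 (-1.10).

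VAT Tregs cultured with IFNα were compared with cultures without it, all with 10 ng/ml IL-33 and 2000 U/ml IL-2, to show what IFNα does to these cells in culture. Pparg was at 3.95 to 7.95 CPM in the cultures, against 17.8 to 122 in the VAT libraries and 0 to 7.76 in the spleen libraries. The cultured cells thus had less Pparg than VAT Tregs taken from mice, and whether their response holds in mice was not tested. Isg15, an antiviral ubiquitin-like gene, went from 7.28 ± 0.415 (SD, n = 3) to 386 ± 12.0 CPM (SD, n = 2) at 50 ng/ml IFNα, a change of 5.72 ± 0.11 (edgeR adjusted p = 2.84e-19). Irf7 changed by 5.17 ± 0.10 and Ifit3 from 0.516 to 841 CPM. Foxp3 (chromosome X, 7573644 to 7595245) fell from 1208 ± 32.2 (SD, n = 3) to 559 ± 5.84 CPM (SD, n = 2), by 1.11 ± 0.073 (adjusted p = 2.82e-10). Klrg1 changed by -0.74 ± 0.079, Ccr2 by -0.68 ± 0.11 and Gata3 by 0.41 ± 0.068 (adjusted p = 5.03e-07, 1.03e-04 and 1.73e-04), while Il1rl1 (-0.15 ± 0.079) did not pass. The calcium-binding gene S100a4 and the lactate transporter gene Slc16a3 changed by -2.04 ± 0.10 and -1.61 ± 0.094. Of 12604 genes 2732 passed, 1342 higher and 1390 lower. Of 44 interferon genes 44 rose (median 3.25, camera adjusted p = 6.94e-04 with an estimated correlation). Glycolysis (19 of 21 lower), cell cycle (20 of 28 lower), NF-kB (11 of 16 higher) and sterol genes (11 of 22 lower) passed only with the preset one (adjusted p = 9.60e-19, 9.80e-08, 5.43e-04 and 5.43e-04, against adjusted p = 0.163, 0.579, 0.165 and 0.253 with an estimated correlation). Il1rl1 gained a call without control replicate 2 (-0.22).

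**Figure D4:**
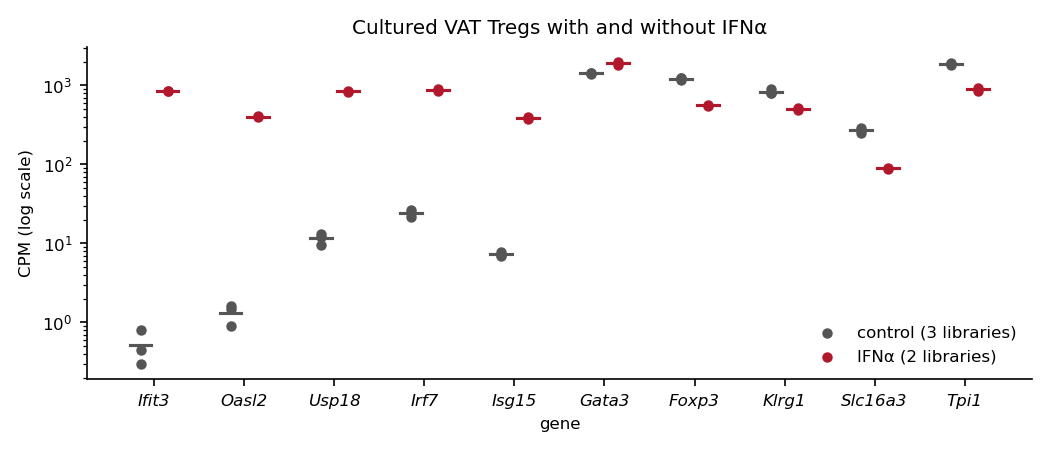
CPM on a log axis of 10 genes in cultured VAT Tregs, 3 libraries without and 2 with IFNα, with bars at the means. Isg15 averages 7.28 CPM without and 386 with IFNα, and Foxp3 1208 and 559.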

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

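Tests in this part chosen only after the result was seen were the differences between week 16 and the earlier weeks in VAT, the fit with a covariate of stress genes, the shift of single libraries against NCD weeks 2, 4 and 8, and the shares of a mixture with the other VAT libraries without HFD as baseline.

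The response to HFD differed between VAT and spleen in a test of the difference itself. By edgeR 380 genes differed, among them Ccr2 (-0.98 on the log2 scale) and Areg (-2.13). Areg had few counts in spleen without HFD, so the size of its difference depends on how low counts are treated. Of 40 random splits of the libraries, 1, the real one, called as many genes, and the highest other called 148. The splits shuffled diet within each tissue and week, so they stand for no diet effect in either tissue. They argue against chance assignment of diet if the libraries are independent. Because an effect shared by both tissues is shuffled away too, they cannot tell whether the response differs between tissues. Tissue is a named difference of the design, and why the response differs between tissues was not tested. The number of genes was 216 without spleen NCD week 4 replicate 2. Areg lost its call without VAT NCD week 16 replicate 2 (-2.07), VAT HFD week 4 replicate 2 (-2.12), VAT HFD week 4 replicate 3 (-2.13), spleen NCD week 2 replicate 2 (-2.01), spleen NCD week 2 replicate 3 (-1.96), spleen NCD week 4 replicate 2 (-1.86), spleen NCD week 8 replicate 1 (-2.03), spleen HFD week 2 replicate 2 (-1.97), spleen HFD week 4 replicate 3 (-2.12), spleen HFD week 8 replicate 1 (-1.98) and spleen HFD week 16 replicate 1 (-1.94), and Ccr2 without VAT NCD week 2 replicate 1 (-0.92), VAT NCD week 4 replicate 1 (-0.95), VAT NCD week 16 replicate 2 (-0.97), VAT NCD week 16 replicate 3 (-0.97), VAT HFD week 4 replicate 2 (-0.96), VAT HFD week 4 replicate 3 (-0.99), VAT HFD week 16 replicate 3 (-0.95), spleen NCD week 2 replicate 3 (-0.93), spleen NCD week 4 replicate 2 (-0.89), spleen NCD week 8 replicate 1 (-0.95), spleen HFD week 2 replicate 1 (-0.89), spleen HFD week 4 replicate 3 (-0.90), spleen HFD week 8 replicate 1 (-0.94) and spleen HFD week 16 replicate 1 (-0.89).

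Within VAT the response at week 16 differed from that at earlier weeks, again by a test of the difference. By edgeR it differed from week 2 in 1032 genes (450 upward, 582 downward), from week 4 in 880 (404 and 476) and from week 8 in 33 (18 and 15). Between weeks 2 and 16 the effect on Pparg moved by -2.20 and on Il10 by -3.97 (adjusted p = 0.00543 and 0.00496). Against week 4 Il10 moved by -4.09 (adjusted p = 0.00595) and Pparg did not pass (-1.45, 0.0886), and against week 8 neither passed (Pparg -1.04, 0.412, and Il10 -3.275, 0.0947). As a list, the VAT-Treg programme moved by a median of -1.62 against week 2, -1.535 against week 4 and -0.97 against week 8 (camera adjusted p = 0.00396, 0.00806 and 0.0262 with an estimated correlation). The immediate early genes moved by -1.57 and -0.95 against weeks 2 and 8 (adjusted p = 0.0107 and 0.0474), and against week 4 (-1.26) they passed only with the preset correlation (adjusted p = 1.26e-10, against adjusted p = 0.0520 with an estimated correlation). The type I interferon and guanylate-binding lists (upward) and the sterol list (downward) passed against each week only with the preset correlation. With an estimated one, camera adjusted p against weeks 2, 4 and 8 was 0.127, 0.0520 and 0.112 for interferon. It was 0.106, 0.0714 and 0.181 for guanylate-binding and 0.106, 0.103 and 0.112 for sterol genes. All these contrasts share the 2 NCD libraries of week 16. Age and the time of sorting run with the week, and neither was tested apart from diet.

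In VAT at week 16 the change with HFD ran toward the expression of spleen Tregs. The NCD libraries of that week standing apart is argued against as the whole cause: with NCD weeks 2, 4 and 8 as baseline, the median change of 1070 genes lower in VAT at week 0 minus that of 1607 genes higher in VAT was 0.522 to 1.14 (log2) in the 3 HFD libraries, above each of the 9 NCD libraries of weeks 2, 4 and 8 set against the other 2 weeks (-0.334 to 0.447), though by little in the lowest. The NCD libraries of week 16 stood at -0.282 and -0.199. The HFD libraries of week 8 stood at 0.684, 0.471 and 0.372, so the shift was not particular to week 16. The HFD mice of week 16 were older than the baseline mice, and age was not tested apart from diet here. Spleen-like Tregs mixed into the HFD libraries would need a share of 0.428 by genes higher in spleen and 0.611 by genes higher in VAT, a difference of -0.183 (95% interval over genes -0.248 to -0.109), with -0.360, -0.172 and -0.109 in the 3 libraries. The bound set for excluding a mixture was met, but it was wrong to set it there, because it assumes that the mixed cells have the spleen profile and that NCD week 16 is the right baseline: with the other libraries as baseline the shares were 0.369 and 0.449 and the difference -0.0809 (-0.145 to -0.0168). A mixture and a change within VAT Tregs therefore cannot be told apart, since no label counts the cells of each kind. Stress of handling stays open too: with the stress genes as a covariate 217 genes were called, but 0.781 of the variance of that covariate lay between groups (8.59 log2 CPM in NCD and 7.28 in HFD at week 16), so the fit removes diet with it.

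Interferon-linked genes were higher with HFD in VAT at week 16. Whether the shift toward spleen is the whole cause stays open. The 94 genes raised by IFNα in culture with little tissue difference at week 0 had a median change of 0.23. This lay above every random set matched on expression (percentile 100, median of random sets -9.10e-04). Little difference was set by a bound and not by a test, and the random sets were not matched on its direction. Genes that respond together also vary more as a set than random genes, so the percentile cannot decide. The 92 genes raised by IFNα in culture that were lower in VAT moved by 1.30, and for these too both readings stay open. Type I interferon acting as in culture would order the genes alike, and across 324 genes (not independent replicates) Spearman's rho was 0.27 (95% interval 0.170 to 0.368) and Pearson's r 0.246, which spans the bound of 0.3 set for it. A response to type I interferon may thus contribute, and it cannot be told apart from type II interferon or another inducer of these genes, since the series has no culture with those.

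For HFD against NCD in VAT, the splits at week 2 (8 genes, highest other 1) and week 8 (189 genes, highest other 0) were 10 each, too few for a share under 0.05, with 1 split calling as many genes at either week. For the mean of the weeks 1 of 100 splits, the real one, called 595 genes and the highest other 25, which argues against chance assignment if the libraries are independent.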

How the results depend on the processing

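Where a count or a direction below moved, the cause was not tested, except where fewer samples or the construction of the alternative is named. VAT against spleen and IFNα in culture kept their counts within 1.5 times with every alternative fixed beforehand and every library left out (8563 to 9441 and 2179 to 2723 genes over the alternatives). So did RLE normalization for all 14 comparisons.

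Without a filter the count was 162 for VAT week 2, 115 for VAT week 4, 465 for VAT week 8, 85, 305, 26 and 26 for spleen weeks 2, 4, 8 and 16, 483 for the spleen mean, 797 for the difference between tissues and 399 for NCD week 16 against week 0. DESeq2 called 70, 61 and 423 genes in VAT at weeks 2, 4 and 8, 37, 307, 1 and 21 in spleen at weeks 2, 4, 8 and 16, 386 for the spleen mean, 631 for the difference between tissues and 342 for time. In the simulated counts of VAT week 16, where genes varied independently, DESeq2 made 21 false calls and edgeR 2. With limma voom the count was 17 at VAT week 2, 11 at VAT week 4 and 388 for time. A fit of only the groups compared, which has fewer libraries to estimate the spread, called 13, 34 and 789 genes in VAT at weeks 2, 4 and 16, 16 and 1 in spleen at weeks 2 and 8, and 830 for time. With the replicate number as a block the count was 29 and 7 at VAT weeks 2 and 4, 396 for the VAT mean, and 13 and 113 at spleen weeks 2 and 4, although the numbers were not shown to pair libraries.

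Among alternatives chosen after seeing the data, the fit without week 4 called 77 genes for the spleen mean and 626 for the difference between tissues, and that without week 16 162 for the VAT mean. The stress-gene covariate left 217 genes at VAT week 16. The covariate of the spleen week 4 genes gave 3 and 38 genes at VAT weeks 2 and 8, 1 for the spleen mean, where it is built from the same libraries, 220 for the difference between tissues and 866 in culture. The GC correction moved none of its 4 counts by over 1.5 times.

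Leaving out 1 library at a time, with fewer samples in each fit, gave 2 to 54 genes at VAT week 2, 0 to 6 at week 4, 37 to 248 at week 8, 643 to 1273 at week 16 and 372 to 657 for the VAT mean. In spleen it gave 0 to 2 genes at week 2, 0 to 268 at week 4, 0 to 7 at week 8, 0 to 1 at week 16 and 16 to 283 for the mean. The difference between tissues ranged from 216 to 477 genes and NCD week 16 against week 0 from 1 to 37. The interferon list in culture and at VAT week 16, the VAT-Treg programme at VAT week 16 and the sterol list in both means kept their direction and side of the threshold in all of these fits with the preset correlation, and the estimated correlation was not run with libraries left out.

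Some directions turned. Without week 16 the mean VAT effect on Il1rl1 was 0.28, and list medians were -0.14 for lymphoid, 0.063 for immediate early and -0.041 for VAT-lower genes, so week 16 set the direction of these means. VAT-higher genes kept a median under 0 (-0.022 against -0.076), and only the direction of the test turned. Hilpda at VAT week 16 was 0.083 with the stress-gene covariate, and oxidative phosphorylation in the spleen mean 0.047 with the covariate of the spleen week 4 genes. With 1 library left out, cell cycle genes at VAT week 8 ran from -0.59 to 0.042 (without NCD replicate 1), cell cycle genes at spleen week 8 from -0.083 (without HFD replicate 2, where the test kept its direction, with -0.077 without NCD replicate 2, where it turned) to 0.87, and VAT-lower genes at spleen week 16 from -0.15 to -0.0067 (without HFD replicate 1, where the direction of the test turned).

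Of the other gene results, with no change of direction, 70 gained and 8 lost a call without a filter, 52 and 2 with DESeq2, 21 and 28 with limma voom, 44 and 21 in fits of only the groups compared, 17 and 32 with the replicate number as a block, and 1 lost it with RLE normalization. With 1 library left out 600 lost, 84 gained and 9297 kept their side of the threshold. Of list results 140 lost and 32 kept their call with an estimated correlation, and with 1 library left out and the preset correlation 155 lost and 2186 kept theirs. Depth limits what low genes can show, since a group at 0 allows up to the CPM worth of 3 counts in each library.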

Other observations

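The test of a library-wide axis in this part was chosen only after the result was seen, as was the fit with that axis as a covariate.

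Genes higher with HFD in spleen at week 4 behaved unlike the other diet results. GC content is argued against as the whole cause, since 189 genes rose with a correction for it and 176 without. A diet effect that lasts beyond week 4 is argued against too: the mean HFD minus NCD difference of these genes was 1.63 at week 4 and -0.0635 over spleen weeks 2, 8 and 16. Outside spleen week 4 the mean of these genes varied between replicates with an SD of 0.31, above every random set matched on expression (percentile 100, median SD 0.028). Genes picked because they moved together vary more as a set than unrelated genes. The percentile thus shows shared variation between libraries of the same group, and not what caused the difference at week 4. That SD is well under the difference of 1.63, but it leaves out shifts between whole groups. In spleen without HFD the mean was 4.646 to 5.225 log2 CPM at week 0 and 5.281 to 5.293 at NCD week 2. It was 4.42 and 4.831 at NCD week 4, 5.832 to 6.012 at NCD week 8 and 5.712 to 6.026 at NCD week 16. The HFD libraries of week 4, at 6.2 to 6.301, thus lay nearer to NCD weeks 8 and 16 than NCD week 4 did. An axis of variation between libraries that is unrelated to diet stays possible. What sets the axis was not tested; it may be technical or a state of the cells, and a short diet effect at week 4 alone stays open.

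The same genes differed by 0.75 (log2) between diets in VAT at week 2, -0.32 at week 4, -0.70 at week 8 and 0.42 at week 16. Of the 176, 114 were higher and 7 lower in VAT than spleen without HFD, with a mean difference of 1.39 (log2) at week 0 and 1.39 at NCD week 4 but 0.176, 0.282 and -0.179 at NCD weeks 2, 8 and 16, and in culture 3 of 174 rose and 63 fell with IFNα.

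For HFD against NCD in spleen the splits at week 2 (4 genes, highest other 1, with 1 split as high), week 8 (0 genes, highest other 0, with 10 as high) and week 16 (0 genes, highest other 28, with 10 as high) were 10 each, too few for a share under 0.05. The 28 genes called by another split at week 16 point to a structure of these 6 libraries that does not follow diet. For the mean of the spleen weeks 1 of 100 splits, the real one, called 137 genes and the highest other 44. For VAT against spleen 1 of 40 called 9221 and the highest other 2. Both argue against chance assignment if the libraries are independent, which the labels do not state. The spleen mean gave 1 gene with the covariate of the spleen week 4 genes, which is built from some of these libraries. A library axis that ran with diet at week 4 thus stays open for it.

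Trbv2, a variable segment of the receptor β chain, made up 87.7 to 97.0% of β variable segment counts in the 26 spleen libraries (median 93.3%), 70.3 to 96.3% in the 25 VAT libraries (median 80.0%) and 3.56 to 6.88% in the 5 cultures. The replicate numbers did not pair libraries throughout: after removing group means, the correlation of libraries with the same number was -0.038 to 0.081 for diet in VAT (10 pairs), -0.041 to 0.16 for diet in spleen (11 pairs) and -0.073 to 0.21 between tissues (24 pairs). At HFD week 16 VAT and spleen libraries of the same number correlated at 0.213, 0.069 and 0.140, and those of different numbers at -0.187 to 0.072. A shared source of these libraries therefore stays open.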
